A study of Drosophila melanogaster with 13 samples.

How the data were processed

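RNA was sequenced from pools of 4 to 8 MN1-Ib motoneurons taken by patch pipette from larvae of instar 3, in 13 libraries. Per the labels' protocols, polyadenylated RNA was copied by template switching, amplified by PCR and read in pairs of 100 bases. No molecular identifier is described, so read counts may also carry variation from amplification. The floor of 3 counts used below covers counting error only, as do the fold limits built on it. The deposited table holds raw read counts per gene for 17753 genes, 1 column per library, as the authors made it. Per the submitters' processing notes, the genome build was BDGP6 and the tools were STAR 2.7.0e, edgeR 3.26.7 and limma 3.40.6 in R 3.6.1. The roles of these tools, the annotation release, the strand setting and the treatment of PCR duplicates and of reads with several matches are not given in the sources used here. Reads of near-identical copies, such as the Hsp70 genes, may therefore be split or lost, and reads of overlapping genes may be shared. Of 61 genes checked, not all those named, 24 overlap another gene with counts, 18 on the other strand and 7 on the same. Mitochondrial genes are among these, as are para and Dh31. Symbols and coordinates come from BDGP6.54, in which 17626 of the gene IDs were found and 127 were not. Of all genes, 4230 had no count in any library.

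Groups were taken from the sample labels: control, Shal RNAi, Notch RNAi and Notch+Shal RNAi. Total counts per library ran from 3783100 to 9319116, so 3 counts, the floor used for genes without counts, equal 0.322 to 0.793 CPM. The test was edgeR 4.0.16 in R 4.3.3: TMM factors, the default low-count filter (minimum count 10, minimum total 15), a robust quasi-likelihood fit of all 13 libraries with 1 estimate of the spread, and 2-sided tests with Benjamini-Hochberg adjustment at 0.05 over 8908 genes. There were 6 comparisons: 3 against control, Notch+Shal RNAi against each single RNAi group, and the interaction. Shal and N were also compared by 2-sided exact permutation tests of normalised CPM. CPM here is scaled to a library's total, and normalised CPM also uses the TMM factor. The median dispersion was 1.36, a biological coefficient of variation of 1.17.

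Before the data were examined, 30 gene lists, the comparisons, the alternatives marked as planned and the rule for named genes were fixed. The lists cover the Notch pathway, Notch targets, potassium channels, Na, Ca and cation channels, pumps and chloride transporters, neuronal transcription factors, motoneuron identity, synaptic release, presynaptic homeostasis, neurotransmitter receptors, cell recognition genes, activity-regulated genes, RNA interference machinery, heat shock genes, the unfolded protein response, innate immune genes, cytoplasmic and mitochondrial ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded RNAs, proteasome, glycolysis, larval sex, construct and landing-site genes, and markers of interneurons, glia, muscle, hemocytes, fat body and neuroblasts. Shal and N are in none of them. Limma 3.58.1 camera compared 29 lists with all other genes at a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation, and fry tested each list by itself. Members were also adjusted over the list alone. Of the listed names, 10 had no match in the table, GFP and GAL4 among them. The rule named Shal, N and nerfin-1 in each comparison, up to 10 genes per direction that passed with a mean of at least 20 CPM in the higher group and a count in each of its libraries, or otherwise the 3 with the lowest p per direction, up to 3 members per direction of each list that passed over all genes or the list alone, and Sh, slo, Shab, para, Kr, Delta and Ser. Other members of lists (DptA, CecB, kuz, Mhc, sls), and senju and roX1, were named after their values were seen.

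The fits were tested on simulated data drawn from the means, library sizes and dispersions of these libraries, with 200 genes changed by known folds. At 16-fold the test recovered 30% of changed genes for Shal RNAi against control (8503 genes), 36% for Notch RNAi against control (8494), 32% for Notch+Shal RNAi against control (8463), 34% against Shal RNAi (8540), 32% against Notch RNAi (8505) and 18% for the interaction (8486). At 8-fold it recovered 12%, 14%, 6%, 8%, 14% and 6% in the same order. With a dispersion of 0.1 it recovered 90 to 100% of 4-fold changes in the first 5 and 66% in the interaction, and all 8-fold changes. At the dispersions of these libraries no simulated call had the wrong direction, and 6, 5, 1, 1, 5 and 7 unchanged genes were called. Camera called 1 of 29 unchanged lists for Shal RNAi against control at these dispersions, 1 of 29 for Notch RNAi against control at a dispersion of 0.1, and none in the other simulations. Simulated genes varied independently, so these simulations cannot show how often camera calls unchanged lists whose members vary together. Alternatives were RLE and TMMwsp factors, no filter and a stricter filter, DESeq2 1.42.0, limma voom with and without sample quality weights, a fit without robust estimation, a replicate block, only the groups compared, and leaving out each library. Added after seeing the data were fits with the roX1 level as a covariate, the older quasi-likelihood method, and fits without Shal RNAi 1 and 3, without the 3 libraries lowest in VGlut, or without the 2 libraries whose w level is out of place, and the fits of lists with TMMwsp or without each library. The fold limits of Sr-CI and Dh31 without each library were added then too. Effects across genes were compared with 100 random regroupings of libraries. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.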

Results

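RNA was measured in MN1-Ib, an identified glutamatergic motoneuron of the Drosophila melanogaster larval body wall, taken from larvae of instar 3 by patch pipette. The cells carried a GFP reporter under a driver active in this neuron. RNA interference was directed in the same neuron at Shal, which encodes the Kv4-type channel of the A-type potassium current, at Notch, the receptor of the Notch signalling pathway, or at both. Each library pooled 4 to 8 cells from 1 or 2 larvae and was an independent reaction. There were 3 control libraries, 3 labelled Shal RNAi, 4 labelled Notch RNAi and 3 labelled Notch+Shal RNAi, named below by group and replicate number. Total gene counts ran from 3783100 in Notch RNAi 3 to 9319116 in Control 2. The labels do not say whether reactions of a group shared larvae, so p-values measure the spread between these reactions. Levels are given as CPM, counts scaled to a library's total, or as normalised CPM, which also carries the TMM factor. Group values are means ± SD, and 3 counts, used as the floor, equal 0.322 to 0.793 CPM by library, for counting error only. The design asks how targeting Shal changes the transcripts of this motoneuron, whether targeting Notch changes them, and whether the response to one depends on the other.

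VGlut, the vesicular glutamate transporter of motoneurons, was present in all 13 libraries at 401 to 2841 CPM, lowest in Notch RNAi 4, Control 3 (476 CPM) and Notch+Shal RNAi 3 (689.9 CPM). Markers of other neurons and of glia differed in level. ChAT, the choline acetyltransferase of cholinergic neurons, reached at most 0.244 CPM, the astrocyte marker alrm had no count in any library, and the glial determinant repo reached 2.44 CPM. Others were present: the glial glutamine synthetase Gs2 was at 16.3 to 755 CPM in all 13 libraries, and VGAT, the vesicular GABA transporter, was detected in 12, at up to 62.7 CPM. The glial genes Eaat1 and moody were each detected in 8 libraries, at up to 61.9 and 76.6 CPM. Transcripts of muscle, hemocytes (blood cells) and fat body were present in most libraries. Mhc, the muscle myosin heavy chain, ranged from 0 to 126 CPM and Hml, the hemocyte clotting factor hemolectin, from 0.266 to 295 CPM. The 10 listed fat body transcripts, larval serum proteins among them, summed to 1539 CPM in Notch+Shal RNAi 2 and 20943 CPM in Notch+Shal RNAi 3. The libraries labelled Shal RNAi detected 7758 ± 427 genes (n = 3) against 9138 ± 119 in control (n = 3), 8408 ± 1007 in Notch RNAi (n = 4) and 9023 ± 225 in Notch+Shal RNAi (n = 3), and Notch RNAi 1 and 2 detected as few (7579 and 7858). Mitochondrially encoded RNA took 10.1 ± 4.25% of counts in Shal RNAi against 2.51 ± 0.110% in control, 3.98 ± 1.56% in Notch RNAi (n = 4) and 2.61 ± 1.92% in Notch+Shal RNAi (n = 3). Shal RNAi 1 and 3 had the highest shares, 13.5% and 11.5% against 5.36% in Shal RNAi 2, and TMM factors of 0.568 and 0.620 against 0.935 to 1.41 elsewhere. Across genes, Spearman's correlation of log2 CPM was 0.786 to 0.876 between libraries of a group and 0.770 to 0.904 between groups, so group members were no closer to each other than to other libraries. No pair of libraries of a group agreed within sampling noise, with chi-square over degrees of freedom of 102 to 495.

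**Figure D1:**
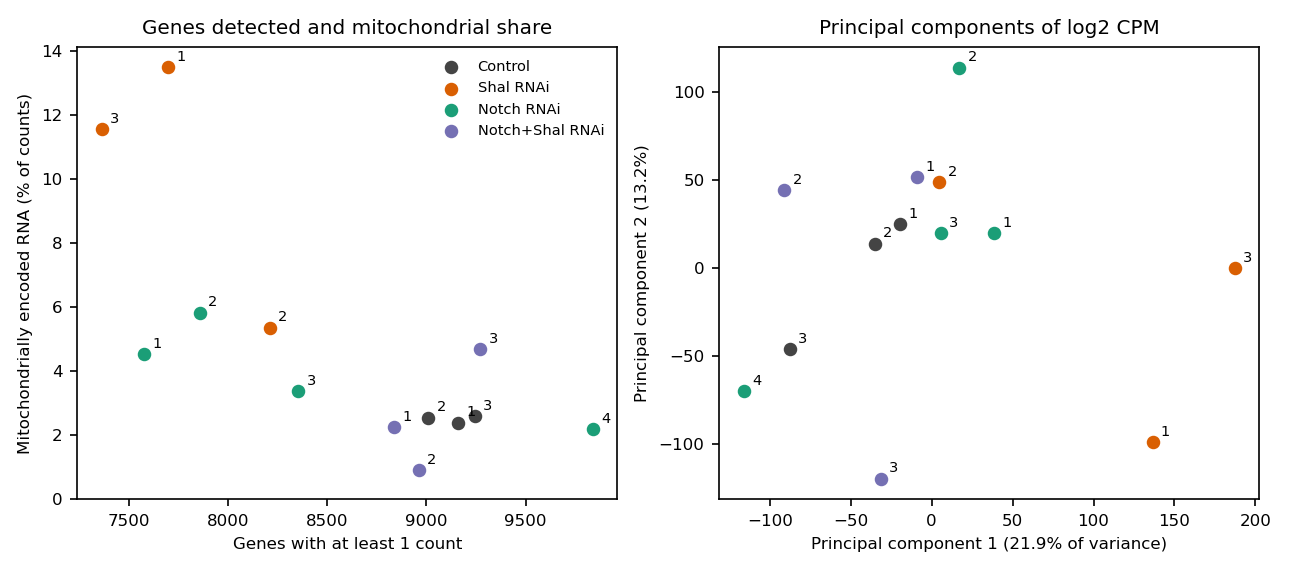
Left, genes with at least 1 count (x axis) against the percent of counts from mitochondrially encoded RNA (y axis) for the 13 libraries, coloured by group and numbered by replicate. Right, principal components 1 and 2 of log2 CPM (21.9% and 13.2% of variance). Shal RNAi 1 and 3 lie highest on the mitochondrial axis, at 13.5% and 11.5%, and farthest to the right on component 1.

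No decrease of an RNA interference target was called in the libraries named for it, so groups are given by label throughout. Shal (FBgn0005564, chromosome 3L, 19566851 to 19584568, BDGP6.54) stood at 41.9 ± 40.2 normalised CPM in control, 139.8 ± 68.1 in Shal RNAi, 46.1 ± 21.1 in Notch RNAi and 40.9 ± 26.5 in Notch+Shal RNAi. Against control it was higher in the libraries labelled Shal RNAi by a log2 fold change of 1.72 (SE 0.83), which did not pass in edgeR (adjusted p = 0.424). A 2-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. In Notch+Shal RNAi the log2 fold change of Shal was -0.05 against control (exact permutation p = 1) and -0.15 against Notch RNAi (exact permutation p = 0.743). N, the gene of Notch (FBgn0004647, chromosome X, 3134870 to 3172221), stood at 79.3 ± 89.8 normalised CPM in control, 15.6 ± 13.3 in Shal RNAi, 68.6 ± 93.8 in Notch RNAi and 126 ± 190.4 in Notch+Shal RNAi. Its log2 fold change against control was -0.16 (SE 1.03, adjusted p = 0.999 in edgeR, exact permutation p = 0.743) in Notch RNAi and 0.64 (exact permutation p = 1) in Notch+Shal RNAi. Against Shal RNAi, N in Notch+Shal RNAi had a log2 fold change of 2.84 (exact permutation p = 0.5), and -0.15 without Notch+Shal RNAi 3. These means rested on 1 library in each of 3 groups, Control 3 at 183, Notch RNAi 4 at 209 and Notch+Shal RNAi 3 at 345 normalised CPM, while the other 10 libraries held 2.09 to 29.3. Without Control 3 the log2 fold change of N in Notch RNAi was 1.38 and without Notch RNAi 4 it was -1.88. Nerfin-1 is a zinc finger transcription factor that maintains neuronal differentiation. Its gene, nerfin-1 (FBgn0028999, chromosome 3L, 909112 to 912319), stood at 25.1 ± 24.5 normalised CPM in control, 5.25 ± 8.74 in Shal RNAi, 118 ± 94.4 in Notch RNAi and 54.4 ± 45.4 in Notch+Shal RNAi. No comparison of nerfin-1 passed. The lowest unadjusted p values were 0.0182 for Notch+Shal RNAi against Shal RNAi (log2 fold change 2.89, SE 1.15, adjusted p = 0.337) and 0.0195 for Notch RNAi against control (2.24, SE 0.90, adjusted p = 0.999).

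**Figure D2:**
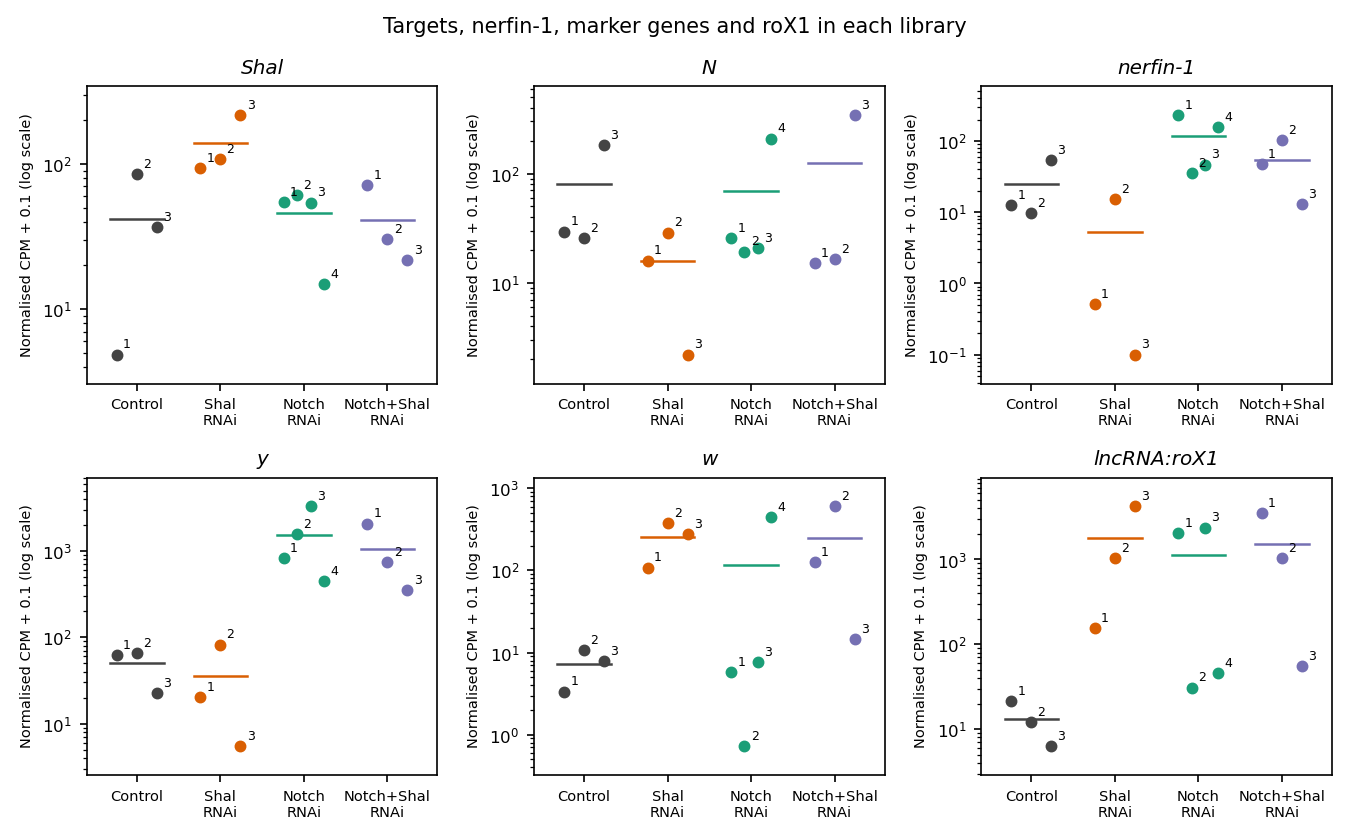
Normalised CPM + 0.1 (log axis) of Shal, N, nerfin-1, the marker genes y and w, and the long non-coding RNA roX1 in each of the 13 libraries, numbered by replicate, with a bar at the group mean. Control 3, Notch RNAi 4 and Notch+Shal RNAi 3 hold N at 183, 209 and 345, and y is at least 353 in every library with a Notch RNAi label and at most 81.9 in the others.

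Shal RNAi against control asks which transcripts of MN1-Ib change when its A-type potassium channel is targeted. Mitochondrially encoded RNAs, which encode respiratory chain subunits and the mitochondrial ribosomal RNAs, were higher as a group (camera adjusted p = 1.52e-21, adjusted p = 0.353 with an estimated correlation). All 17 tested members lay above 0, with a median log2 fold change of 3.23, and 14 passed when adjusted over the list alone, none over all genes. The gene mt:ATPase6, a subunit of ATP synthase, went from 3008 ± 523 to 28281 ± 18917 normalised CPM (n = 3 each, log2 fold change 3.23, SE 0.71). The genes mt:ND4 and mt:ND1, subunits of complex I, had log2 fold changes of 3.75 and 4.03. Synaptic release genes, Na, Ca and cation channels and neurotransmitter receptors also lay higher, and proteasome subunits lower (adjusted p = 0.417 for each with an estimated correlation). Among single genes EndoA (endophilin A, for synaptic vesicle endocytosis) went from 16.4 ± 10.1 to 179 ± 62.1, Mctp (a C2-domain protein of presynaptic homeostatic plasticity) from 1.46 ± 1.39 to 75.0 ± 68.6, and para (the voltage-gated sodium channel) from 541 ± 277 to 3587 ± 2182 normalised CPM, and each rose when adjusted over its list alone.

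By group, the list of mitochondrially encoded RNAs differed from other genes in limma's camera test (adjusted p = 1.52e-21 at a preset correlation of 0.01, adjusted p = 0.353 with an estimated correlation). Beside it, these same libraries detected fewer genes than control, as above. Over 8827 nuclear genes the log2 fold change rose with expression level (Spearman rho 0.316), and camera takes no account of level. Nuclear lists matched to the mitochondrial RNAs on exon length and level had medians that averaged 0.54. How far the shifts of the other lists follow level was not tested in any comparison. 25 of 29 synaptic release genes were higher (median 1.01, camera adjusted p = 2.19e-07, adjusted p = 0.417 with an estimated correlation), and 2 passed adjusted over the list alone: EndoA (log2 fold change 3.41, SE 0.84, adjusted p = 0.0118) and Synj, the lipid phosphatase synaptojanin (3.09, adjusted p = 0.0192). By CPM, where mitochondrial RNA takes part of the total, the synaptic release list summed to 15395, 21591 and 19818 in Shal RNAi 1 to 3 and 17178, 19523 and 12043 in Control 1 to 3. 47 of 72 nuclear genes of oxidative phosphorylation were higher (median 0.47, camera adjusted p = 2.05e-06, adjusted p = 0.417 with an estimated correlation), and 7 rose adjusted over the list alone, among them the complex III subunits UQCR-11 (2.94), UQCR-6.4 (3.09) and ox (2.75). 32 of 34 proteasome subunits were lower (median -1.001, camera adjusted p = 4.90e-06, adjusted p = 0.417 with an estimated correlation) and 0 passed adjusted over the list alone. That list summed to 2682 and 2293 CPM in Shal RNAi 1 and 3, 9088 in Shal RNAi 2 and 8565 to 15804 elsewhere. 13 of 17 Na, Ca and cation channel genes were higher (median 0.95, camera adjusted p = 0.00178, adjusted p = 0.417 with an estimated correlation), of which para passed over the list alone (log2 fold change 2.73, SE 0.76, adjusted p = 0.0222). 22 of 30 neurotransmitter receptors were higher (median 0.88, camera adjusted p = 0.00221, adjusted p = 0.417 with an estimated correlation), with none passing alone. Leaving out 1 library at a time kept these calls, with medians of 0.0990 to 0.68 for oxidative phosphorylation (lowest without Shal RNAi 3), -1.61 to -0.75 for proteasome, 0.63 to 1.27 for the channels and 0.56 to 1.04 for receptors. Without Shal RNAi 1 and 3 together, which leaves 1 Shal RNAi library that is assumed to vary like the other groups, the camera adjusted p was 0.0692 for oxidative phosphorylation, 0.142 for proteasome and 0.0755 for the channels, and the mitochondrially encoded median was 1.37.

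Smaller shifts were called for neuronal transcription factors (median 0.80, or 0.67 with members lacking counts in a group set at their bound, camera adjusted p = 0.0166), glycolysis (0.26, 0.0166), mitochondrial ribosomal proteins (0.11, 0.00965), fat body transcripts (0.64, 0.0179) and motoneuron identity genes (0.70, 0.0461). Their adjusted p was 0.417 to 0.482 with an estimated correlation. Where a call was lost, all medians means the range of a list's median with each library of the comparison left out in turn. The call was lost for the transcription factors without Control 2 or Shal RNAi 1 (adjusted p up to 0.155, all medians 0.18 to 1.1996). It was lost for the ribosomal proteins without Shal RNAi 3 (adjusted p up to 0.0734, all medians 0.00398 to 0.31). Glycolysis was lost without Control 1 or 3 or Shal RNAi 2 or 3 (adjusted p up to 0.318, all medians -0.28 to 1.66). Fat body was lost without Control 1 or 3 or Shal RNAi 1 (adjusted p up to 0.147, all medians 0.28 to 1.53). Motoneuron identity was lost without Control 1 or 3 or Shal RNAi 1 or 3 (adjusted p up to 0.147, all medians 0.35 to 1.11). Adjusted over the list alone, 4 of 26 Notch pathway genes rose, with a list median of 0.08 and a camera adjusted p of 0.165. They include gro, the corepressor Groucho (2.43), pen-2, a subunit of the gamma-secretase that cleaves Notch (2.37), and numb, an inhibitor of Notch (3.31, 8.64 ± 9.76 to 84.7 ± 57.7 normalised CPM). The gene pum, the translational repressor Pumilio, rose by the same measure (2.61, adjusted p = 0.0468). Heat shock genes went both ways. Hsp70Bb rose (469 ± 139.8 to 4575 ± 2699 normalised CPM, log2 fold change 3.29, SE 0.66, adjusted p = 4.58e-04 over the list alone and 0.145 over all genes), as did its near-identical copies Hsp70Ba (4.66) and Hsp70Ab, whose reads may be split between copies by the counting. Hsp27 fell by 1.80 on the log2 scale (1924 ± 1199 to 551 ± 335). The glial receptor gene moody passed over its list alone from Shal RNAi 3, which held 124 normalised CPM against at most 0.250 in the other libraries compared.

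The excitability genes chosen in advance did not pass over all genes. Sh, the Shaker potassium channel, stood at 883 ± 275 and 1707 ± 312 normalised CPM (log2 fold change 0.95, SE 0.58, unadjusted p = 0.111). The calcium-activated potassium channel slo had a log2 fold change of 1.52 (adjusted p = 0.448 in edgeR) and the delayed rectifier Shab 1.56 (adjusted p = 0.399). 13 of 18 potassium channel genes were higher (median 0.34, camera adjusted p = 0.0851), which is not a call. The transcription factor Kr (Krüppel) had 1.38 (adjusted p = 0.564), and the Notch ligands Delta and Ser had -2.52 (adjusted p = 0.639) and 1.504 (adjusted p = 0.715). In edgeR, 0 of 8908 genes passed an adjusted p of 0.05 and 1047 had an unadjusted p under 0.05, 716 higher and 331 lower, against 445 expected. Without Shal RNAi 2 the count was 146, and without Control 3 it was 1. DESeq2 called 309 genes (162 higher, 147 lower), limma voom 0 and voom with sample quality weights 25. The median log2 fold change over all genes was -0.27, and -0.02 with TMMwsp scaling. The lowest p among lower genes were those of the trypsin epsilonTry (-7.06, Control 2 alone at 1773 normalised CPM, and 4.14 without it), the chromatin protein gene Arp6 (-3.79, 71.6 ± 21.2 to 4.43 ± 4.07) and CG12945 (-5.08, 45.9 ± 15.6 to 2.07 ± 2.49), and none passed. Of the single genes passing over their lists alone, Mctp (adjusted p = 0.00230), Hsp70Bb and the 3 named mitochondrial genes passed whichever library was left out. EndoA was lost without Control 1 or 3 (adjusted p up to 0.0736), para without Control 1 or 3 or Shal RNAi 1 or 3 (adjusted p up to 0.177) and Hsp70Ba without Control 3 or Shal RNAi 3 (adjusted p up to 0.0551). Hsp70Ab was lost without Control 3 (adjusted p up to 0.0551), Hsp27 without Control 3 or Shal RNAi 1 or 3 (adjusted p up to 0.315) and moody without Control 2 or 3 or Shal RNAi 3 (adjusted p up to 0.925). The genes pum, gro, pen-2, Synj, UQCR-11, UQCR-6.4 and ox were each lost without any 1 of Control 1 to 3 or Shal RNAi 1 or 3, and numb without any 1 of the 6 libraries (adjusted p up to 0.433 in pen-2).

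Notch RNAi against control asks what targeting Notch alone does to this neuron. The gene with the lowest p was y, whose product yellow acts in cuticle pigmentation and which marks many transgene landing-site chromosomes (FBgn0004034, chromosome X, 356509 to 361245). It went from 49.7 ± 23.7 normalised CPM in control (n = 3) to 1539 ± 1264 in Notch RNAi (n = 4), a log2 fold change of 4.95 (SE 0.89), and rose when adjusted over its list alone (adjusted p = 4.75e-05) but not over all genes (0.0595). Glycolysis genes were lower as a group, with all 13 members below 0 (median -1.26, camera adjusted p = 5.16e-06, adjusted p = 0.420 with an estimated correlation), and lost that call without Control 2 (adjusted p up to 0.456, all medians -1.70 to -0.17), with a median of -0.17 there. Antimicrobial peptide and immune genes were higher (11 of 15, median 1.70, camera adjusted p = 2.72e-04, adjusted p = 0.420 with an estimated correlation). The immune genes with the lowest p were the peptides DptA (Diptericin A, means of 0.0832 and 13.5 normalised CPM) and CecB (Cecropin B, 0 and 6.67), neither of which passed. Potassium channel genes lay higher in 15 of 18 and Notch pathway genes in 20 of 26 (adjusted p = 0.420 for both with an estimated correlation). N itself had a log2 fold change that changed sign between left-out libraries, as above.

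Camera called 11 lists. The glycolysis and immune lists are given above. The immune list had a median of 1.38 with members lacking counts in a group at their bound, and was lost without Notch RNAi 1 (adjusted p up to 0.425, all medians -0.0252 to 4.93), with a median of -0.03 there. Higher lists were potassium channels (median 0.50, camera adjusted p = 0.0162), neuronal transcription factors (0.44, 0.0162), mitochondrially encoded RNAs (0.88, 0.0182), activity-regulated genes (0.60, 0.0287), neurotransmitter receptors (0.40, 0.0349), the Notch pathway (0.55, 0.0421) and pumps and chloride transporters (0.38, 0.0421). Their adjusted p was 0.420 to 0.759 with an estimated correlation. Lower lists were muscle markers (-0.46, 0.0162) and nuclear oxidative phosphorylation genes (-0.32, 0.0421). With an estimated correlation none of the 11 was called, the adjusted p being 0.42 to 0.819. Each of these 9 lists was lost on leaving out single libraries: potassium channels without Control 3 or Notch RNAi 2 or 3 (adjusted p up to 0.299, all medians 0.28 to 1.17) and transcription factors without Control 2 or Notch RNAi 1 (adjusted p up to 0.252, all medians 0.32 to 0.62). Mitochondrial RNAs were lost without Control 1 or Notch RNAi 1 or 2 (adjusted p up to 0.541, all medians 0.41 to 1.14). Activity-regulated genes were lost without Control 1 or 3 or Notch RNAi 2 or 3 (adjusted p up to 0.174, all medians 0.15 to 0.89). Receptors were lost without Control 3 or Notch RNAi 1, 2 or 3 (adjusted p up to 0.671, all medians 0.0590 to 0.67). The Notch pathway was lost without Control 1 or 2 or Notch RNAi 1, 3 or 4 (adjusted p up to 0.353, all medians 0.00339 to 0.95). Pumps were lost without Control 1 or 3 or Notch RNAi 2 or 3 (adjusted p up to 0.661, all medians 0.00241 to 0.68), muscle without Control 2 or 3 or Notch RNAi 1 or 4 (adjusted p up to 0.479, all medians -1.46 to -0.14). Oxidative phosphorylation was lost without Control 2 or Notch RNAi 1 or 4 (adjusted p up to 0.968, all medians -0.47 to 0.0454). The oxidative phosphorylation list was also lost with TMMwsp scaling (adjusted p = 0.233).

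Adjusted over the list alone, y was the only member of any list to pass, and it passed whichever library was left out. Among Notch pathway genes the lowest p was that of kuz, the Kuzbanian protease that cleaves Notch (log2 fold change 1.73). Of 15 tested Notch target genes, the E(spl) complex among them, 12 were lower (median -0.73, camera adjusted p = 0.281), which is not a call. Other genes with the lowest p were spz, the Toll ligand Spätzle (2.85, adjusted p = 0.999 in edgeR), and CG8861 (4.02) among those higher, and epsilonTry (-8.68, adjusted p = 0.0595), the cuticle protein gene Lcp1 (-2.96, 3149 ± 2201 to 404 ± 170.4) and the protease Jon74E (-5.98) among those lower. The values of epsilonTry and Jon74E came from Control 2, and without it their log2 fold changes were 2.53 and 3.75. EdgeR called 0 of 8908 genes, with 386 at an unadjusted p under 0.05 (170 higher, 216 lower), DESeq2 32 (13 higher, 19 lower), limma voom 0 and voom with sample quality weights 1. Without Control 1 or Control 3 edgeR called 2 genes, and without Notch RNAi 4 it called 1.

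Notch+Shal RNAi against control asks how the neuron differs when both genes are targeted. Muscle transcripts, such as the myosin heavy chain Mhc (log2 fold change -2.39) and the titin relative sls (-1.88), were lower as a group, in 18 of 18 members with a median of -1.44 (camera adjusted p = 9.99e-12, adjusted p = 0.308 with an estimated correlation). The muscle list summed to 1135, 428 and 1719 CPM in Notch+Shal RNAi 1 to 3 and 1212, 3964 and 3963 CPM in Control 1 to 3. Muscle and hemocyte genes mark other cells, and whether their transcripts came from the neuron was not tested in any comparison. Hemocyte transcripts were higher in 10 of 13 (median 2.12, camera adjusted p = 2.67e-04, adjusted p = 0.412 with an estimated correlation), and 3 rose when adjusted over the list alone: Hml (7.46 ± 4.25 to 132 ± 156 normalised CPM, n = 3 each, log2 fold change 4.09, SE 1.08), the phagocytosis receptor eater (3.98) and the type IV collagen Col4a1 (3.59). Again y was higher, from 49.7 ± 23.7 to 1058 ± 904 (4.41, SE 0.88, adjusted p = 2.13e-04 over the list alone and 0.237 over all genes), and so was w, the white gene used as an eye-colour transgene marker (5.08, adjusted p = 0.0449 over the list alone). Mitochondrially encoded RNAs had a median of 0.14 and synaptic release genes of 0.12 here, neither called (camera adjusted p = 0.376 and 0.627). No decrease of Shal or N was called in these libraries, and N had a log2 fold change of -2.34 without Notch+Shal RNAi 3.

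The muscle list was called by camera (adjusted p = 9.99e-12, adjusted p = 0.308 with an estimated correlation) whichever library was left out, with 0 members passing adjusted over the list alone. The hemocyte list (camera adjusted p = 2.67e-04, adjusted p = 0.412 with an estimated correlation) rested on Notch+Shal RNAi 3, which held Hml at 295 CPM. Without that library its median was 0.47 and its adjusted p 0.531, and Hml, eater and Col4a1 no longer passed (adjusted p = 0.188). Hml was also lost without Control 3, and eater and Col4a1 without Control 1 or 3. Heat shock genes were higher in 11 of 12 (median 0.55, camera adjusted p = 0.00896, adjusted p = 0.308 with an estimated correlation), lost without Notch+Shal RNAi 2 (adjusted p up to 0.358, all medians 0.14 to 1.17). Glycolysis was lower in 11 of 13 (median -0.60, camera adjusted p = 0.0396, adjusted p = 0.834 with an estimated correlation), lost without Control 2 or Notch+Shal RNAi 1 or 3 (adjusted p up to 0.745, all medians -1.48 to 0.37). The list of construct and landing-site genes had a median of 0.86 (camera adjusted p = 0.0396, adjusted p = 0.308 with an estimated correlation), lost without Control 2 or 3 or Notch+Shal RNAi 1 or 2 (adjusted p up to 0.157, all medians 0.47 to 1.21). In it w was lost without Control 1, 2 or 3 or Notch+Shal RNAi 1 or 2 (adjusted p up to 0.182), and y was not lost without any 1 library. The receptor-like genes mthl6 (5.66) and mthl8 had low p values in opposite directions. Notch+Shal RNAi 3 alone held mthl6 at 325 normalised CPM, and mthl8 went from 29.8 ± 25.4 to 0.0293 ± 0.0507. The proteases epsilonTry (-8.99) and Jon74E (-7.62) again rested on Control 2, with 2.22 and 2.11 without it. EdgeR called 0 genes, with 382 at an unadjusted p under 0.05 (241 higher, 141 lower), DESeq2 24 (11 higher, 13 lower) and limma voom 0 with or without quality weights. Without Control 1 or Control 3 edgeR called 1 gene.

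Notch+Shal RNAi against Shal RNAi asks what targeting Notch adds where Shal is already targeted. Mitochondrially encoded RNAs were lower in 17 of 17 members (median -3.14, camera adjusted p = 1.68e-24, adjusted p = 0.265 with an estimated correlation), with 15 passing over the list alone: mt:ND1 went from 3883 ± 2509 to 336 ± 397 normalised CPM (n = 3 each, log2 fold change -3.54, SE 0.87), mt:ATPase6 had -2.96 and mt:ATPase8 -3.14. Synaptic release genes were lower in 24 of 29 (median -0.73) and proteasome genes higher in 33 of 34 (median 0.95; adjusted p = 0.459 for both with an estimated correlation). Adjusted over their lists alone, EndoA (log2 fold change -3.12), Mctp (-5.42), para (-2.62), the dopamine receptor gene Dop2R (-4.49) and the cell recognition gene dpr21 (-2.76) fell. Muscle markers were lower in 17 of 18 (median -1.63) and glycolysis in 11 of 13 (median -0.81; adjusted p = 0.459 for both with an estimated correlation). Of the latter, hexokinase A (Hex-A, -3.24) and lactate dehydrogenase (Ldh, -3.79) fell adjusted over the list alone. This comparison shares its Shal RNAi libraries with the one against control. Those libraries detected 7758 ± 427 genes against 9023 ± 225 in Notch+Shal RNAi, and Shal RNAi 1 and 3 had TMM factors of 0.568 and 0.620. The design does not tell the RNAi labels apart from such differences between libraries, and yield itself was not measured.

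Camera called 10 lists at the preset correlation: mitochondrially encoded RNAs (adjusted p = 1.68e-24, adjusted p = 0.265 with an estimated correlation), nuclear oxidative phosphorylation (median -0.63, 3.19e-09), muscle (5.54e-08), synaptic release (9.22e-07), proteasome (8.74e-06), mitochondrial ribosomal proteins (-0.58, 3.99e-05), glycolysis (4.18e-05), neurotransmitter receptors (-0.48, 0.00528), neuroblast and cell cycle genes (2.26, 0.0103) and Na, Ca and cation channels (-0.52, 0.0123). For the last 9 the adjusted p was 0.459 to 0.472 with an estimated correlation. The receptors were lost without Notch+Shal RNAi 3 (adjusted p up to 0.357, all medians -0.92 to -0.29), the channels without Shal RNAi 3 or Notch+Shal RNAi 3 (adjusted p up to 0.170, all medians -0.91 to -0.15) and the neuroblast list without Notch+Shal RNAi 3 (adjusted p up to 0.170, all medians 0.93 to 6.002), and the neuroblast median was 1.85 with members lacking counts in a group at their bound. The other 7 stayed called whichever library was left out, with medians of -4.46 to -2.70 for mitochondrially encoded RNAs, -0.72 to -0.39 for oxidative phosphorylation, -2.51 to -1.27 for muscle and -1.10 to -0.37 for synaptic release. They were 0.75 to 1.66 for proteasome, -0.89 to -0.30 for mitochondrial ribosomal proteins and -1.85 to -0.53 for glycolysis. Without Shal RNAi 1 and 3 together, which leaves 1 Shal RNAi library that is assumed to vary like the other groups, the proteasome adjusted p was 0.360 and the channel median 0.20. The level of y was again higher (35.9 ± 40.6 to 1058 ± 904, log2 fold change 4.73, adjusted p = 0.197 over all genes). Dh31, a diuretic neuropeptide gene, had 0 counts in the libraries labelled Shal RNAi and 151 ± 168 normalised CPM in Notch+Shal RNAi, at least 180-fold higher with a floor of 3 counts per library (68-fold without Notch+Shal RNAi 2), and did not pass. Its span overlaps that of Bace on the same strand. Also not passing were ktub (the tubby relative, 5.04), lncRNA:CR34335 (-3.69), mthl8 (91.3 ± 81.4 to 0.0293 ± 0.0507) and the immune-induced IM33 (149.8 ± 44.0 to 3.59 ± 4.80).

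Hemocyte genes eater (5.999), Sr-CI (a scavenger receptor, 4.91) and Hml (3.37) and the chaperone Hsp27 (2.05) rose, and Hsp70Bb (-1.94), UQCR-11 (-2.81), UQCR-6.4 (-2.84) and moody (41.3 ± 71.5 to 0.478 ± 0.754 normalised CPM) fell, each adjusted over its list alone in edgeR. The mitochondrial genes and y passed whichever library was left out. Mctp was lost without Shal RNAi 1 (adjusted p up to 0.0587), Hex-A without Shal RNAi 3 (adjusted p up to 0.0762) and para without Shal RNAi 1 or 3 or Notch+Shal RNAi 2 or 3 (adjusted p up to 0.188). EndoA was lost without Shal RNAi 1 or 3 or Notch+Shal RNAi 1, 2 or 3 (adjusted p up to 0.0972) and Dop2R without Shal RNAi 1 or 3 or Notch+Shal RNAi 1, 2 or 3 (adjusted p up to 0.218). The gene dpr21 was lost without Shal RNAi 1 or 3 or Notch+Shal RNAi 2 or 3 (adjusted p up to 0.163) and Ldh without Shal RNAi 2 or 3 or Notch+Shal RNAi 1 or 3 (adjusted p up to 0.139). The receptor gene eater was lost without Shal RNAi 1, 2 or 3 or Notch+Shal RNAi 3 (adjusted p up to 0.103) and Sr-CI without Shal RNAi 1, 2 or 3 or Notch+Shal RNAi 3 (adjusted p up to 0.147). Hml was lost without Shal RNAi 1 or 2 or Notch+Shal RNAi 3 (adjusted p up to 0.245) and Hsp27 without Shal RNAi 1 or 3 or Notch+Shal RNAi 3 (adjusted p up to 0.147). Hsp70Bb was lost without Shal RNAi 1 or 3 or Notch+Shal RNAi 2 or 3 (adjusted p up to 0.147), UQCR-11 and UQCR-6.4 without Shal RNAi 1 or 3 or Notch+Shal RNAi 1 or 2 (adjusted p up to 0.272). The gene moody was lost without Shal RNAi 3 or Notch+Shal RNAi 1, 2 or 3 (adjusted p up to 1.00). EdgeR called 0 of 8908 genes, with 1092 at an unadjusted p under 0.05 (495 higher, 597 lower), DESeq2 307 (183 higher, 124 lower) and limma voom 0 with or without quality weights. Without Shal RNAi 2 edgeR called 26 genes. The median log2 fold change over all genes was 0.38, and 0.15 with TMMwsp scaling.

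Notch+Shal RNAi against Notch RNAi asks what targeting Shal adds where Notch is already targeted. Hemocyte transcripts were higher in 12 of 13 (median 1.89, camera adjusted p = 4.40e-05, adjusted p = 0.841 with an estimated correlation), and Sr-CI, Hml and eater rose adjusted over the list alone (adjusted p = 8.89e-04, 0.00443 and 0.0225). Sr-CI had 0 counts in the 4 Notch RNAi libraries and 76.4 ± 80.0 normalised CPM in Notch+Shal RNAi (n = 3), at least 165-fold higher with a floor of 3 counts per library (74-fold without Notch+Shal RNAi 3), and its adjusted p over all genes was 0.440. Mitochondrially encoded RNAs were lower in 13 of 17 (median -0.60, adjusted p = 0.841 with an estimated correlation), where Shal RNAi against control had all 17 higher. Muscle markers were lower in 17 of 18 (-0.81) and potassium channels in 14 of 18 (-0.38). For these 2 lists the adjusted p was 0.841 with an estimated correlation, and leaving out 1 library brought the medians as near 0 as -0.0355 and -0.0115.

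Camera called 8 lists, and for all 8 the adjusted p was 0.841 with an estimated correlation. These were hemocyte markers (camera adjusted p = 4.40e-05), mitochondrially encoded RNAs (4.42e-04), muscle markers (5.37e-04), fat body transcripts (median 1.11, 0.0265), glycolysis (0.47, 0.0430), immune genes (-1.14, 0.0495), potassium channels (0.0495) and proteasome subunits, with a median of -0.20 and a mean of 0.08 (0.0495). Each was lost on leaving out single libraries: hemocytes without Notch+Shal RNAi 3 (adjusted p up to 0.487, all medians 0.16 to 2.72) and mitochondrial RNAs without Notch RNAi 1 or Notch+Shal RNAi 2 (adjusted p up to 0.588, all medians -1.503 to -0.0954). Muscle was lost without Notch RNAi 2 or Notch+Shal RNAi 2 (adjusted p up to 0.836, all medians -1.55 to -0.0355). Fat body was lost without Notch RNAi 1 or 2 or Notch+Shal RNAi 1 or 3 (adjusted p up to 0.902, all medians 0.39 to 1.599). Glycolysis was lost without Notch RNAi 1 or 4 or Notch+Shal RNAi 2 (adjusted p up to 0.966, all medians -0.19 to 1.02). The immune list was lost without Notch RNAi 1, 3 or 4 or Notch+Shal RNAi 1 or 2 (adjusted p up to 0.948, all medians -3.83 to 0.0970), and its median changed sign without Notch RNAi 1. Potassium channels were lost without Notch RNAi 1, 2 or 3 or Notch+Shal RNAi 1 or 3 (adjusted p up to 0.440, all medians -0.76 to -0.0115) and proteasome without Notch RNAi 1, 2 or 4 or Notch+Shal RNAi 2 or 3 (adjusted p up to 0.902, all medians -0.35 to -0.00261). Immune genes were also lost with RLE and TMMwsp scaling (adjusted p = 0.0516 and 0.0722), glycolysis with TMMwsp (0.0610), and potassium channels and proteasome with RLE (0.0516 each). Sr-CI passed over its list alone whichever library was left out, Hml was lost without Notch+Shal RNAi 3 (adjusted p up to 0.260) and eater without Notch RNAi 1, 2 or 3 or Notch+Shal RNAi 3 (adjusted p up to 0.260). Genes with the lowest p that did not pass were CG10031 (5.73) and mthl6 (6.91) among those higher, and Jhbp2, a juvenile hormone binding protein (-3.37), CG12934 (-6.46) and the peroxisome gene Pex2 (-3.27) among those lower. EdgeR called 0 of 8908 genes, with 431 at an unadjusted p under 0.05 (305 higher, 126 lower), DESeq2 33 (18 higher, 15 lower) and limma voom 0 with or without quality weights. Without Notch+Shal RNAi 2 edgeR called 2.

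The interaction asks whether the difference linked to the Shal RNAi label depends on the Notch RNAi label. A negative value means that Shal RNAi raised a gene less, or lowered it more, in libraries with a Notch RNAi label. Mitochondrially encoded RNAs had the most negative list median of those called (-3.57, 17 of 17 below 0, camera adjusted p = 6.19e-24, adjusted p = 0.273 with an estimated correlation), and 13 of them passed adjusted over the list alone, among them mt:ATPase6 (-3.83, SE 0.93), mt:ND1 (-4.78) and mt:Cyt-b, cytochrome b of complex III (-3.57). Shal RNAi 1 and 3, which held 13.5% and 11.5% mitochondrial RNA, had TMM factors of 0.568 and 0.620 against 0.935 to 1.41 elsewhere. The interaction is therefore not told apart from library yield. It and the comparisons with control may also carry differences in roX1, as no control library had a high level. Synaptic release genes were below 0 in 21 of 29 (median -0.91, camera adjusted p = 1.03e-04, adjusted p = 0.441 with an estimated correlation), with EndoA passing over the list alone (-4.04, adjusted p = 0.0483). So did Mctp (-7.12, adjusted p = 0.0187), dpr21 (-3.75) and Hsp70Bb (-3.29), while Sr-CI passed with a positive value that is a fitted number and no bound, since its Notch RNAi libraries had no counts. Potassium channel genes were below 0 in 13 of 18 (median -0.80, adjusted p = 0.441 with an estimated correlation), led by Sh (log2 interaction -1.99, SE 0.80, unadjusted p = 0.0189, adjusted p = 0.476). The sodium channel para had -2.99 (SE 1.00, unadjusted p = 0.00621, adjusted p = 0.452), and neither it nor Sh passed.

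Camera called 13 lists. Mitochondrially encoded RNAs (adjusted p = 6.19e-24, adjusted p = 0.273 with an estimated correlation), synaptic release genes (1.03e-04, adjusted p = 0.441 with an estimated correlation) and nuclear oxidative phosphorylation genes (median -0.38, 3.79e-04, adjusted p = 0.531 with an estimated correlation) stayed called whichever of the 13 libraries was left out, the last with medians of -0.59 to -0.0987. Without Shal RNAi 1 and 3 together, which leaves 1 Shal RNAi library that is assumed to vary like the other groups, the oxidative phosphorylation adjusted p was 0.239 and the mitochondrially encoded median -1.94. The other 10, whose adjusted p was 0.441 to 0.561 with an estimated correlation, were neurotransmitter receptors (median -0.74, camera adjusted p = 8.70e-04), muscle markers (-1.14, 0.00535), mitochondrial ribosomal proteins (-0.21, 0.00535), neuronal transcription factors (-0.38, or -0.27 with members lacking counts in a group at their bound, 0.0101), neuroblast and cell cycle genes (2.74, or 1.75 at the bound, 0.0121), potassium channels (0.0121), proteasome (0.74, 0.0129), Na, Ca and cation channels (-0.87, 0.0129), pumps and chloride transporters (median -0.95, mean 0.07, 0.0204) and cell recognition genes (-0.21, 0.0393). Receptors were lost without Notch+Shal RNAi 3 (adjusted p up to 0.0690, all medians -1.47 to -0.39) and muscle without Notch RNAi 2 or Notch+Shal RNAi 2 (adjusted p up to 0.169, all medians -1.81 to -0.34). Mitochondrial ribosomal proteins were lost without Notch+Shal RNAi 2 (adjusted p up to 0.196, all medians -0.73 to 0.00704). The call was lost for transcription factors without Control 2 (adjusted p up to 0.0610, all medians -1.27 to -0.0381) and neuroblast genes without Control 3 or Notch+Shal RNAi 3 (adjusted p up to 0.173, all medians 0.90 to 6.07). Potassium channels were lost without Control 3, Shal RNAi 3 or Notch+Shal RNAi 3 (adjusted p up to 0.0690, all medians -1.14 to -0.50) and proteasome without Shal RNAi 1 or 3, Notch RNAi 4 or Notch+Shal RNAi 1 (adjusted p up to 0.136, all medians 0.50 to 1.21). Na, Ca and cation channels were lost without Control 3, Shal RNAi 3, Notch RNAi 2 or Notch+Shal RNAi 3 (adjusted p up to 0.117, all medians -1.15 to -0.35). Pumps were lost without Control 1 or 3, Shal RNAi 2, Notch RNAi 2 or Notch+Shal RNAi 3 (adjusted p up to 0.218, all medians -1.16 to -0.68). Cell recognition genes were lost without Control 2 or 3, Shal RNAi 1 or 3, Notch RNAi 2 or 3 or Notch+Shal RNAi 3 (adjusted p up to 0.512, all medians -1.23 to 0.26). The proteasome was also lost with TMMwsp scaling (adjusted p = 0.0988).

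Other genes chosen in advance had log2 interactions of -1.39 (slo), -1.64 (Shab), -1.34 (Kr), 2.83 (Delta), -2.44 (Ser), 3.00 (N) and 0.64 (nerfin-1), and none passed. Those with the lowest p were CG8089 (0.0994 ± 0.172 normalised CPM in Shal RNAi and 35.6 ± 31.1 in Notch+Shal RNAi), CG12316 (0.0994 ± 0.172 and 50.7 ± 32.2) and Tdrd3, a Tudor-domain protein gene (6.33), on the positive side, and CanA-14F, a calcineurin catalytic subunit (-4.20), on the negative side. EdgeR called 0 of 8908 genes, with 813 at an unadjusted p under 0.05 (388 positive, 425 negative), DESeq2 118 (79 positive, 39 negative) and limma voom 0 with or without quality weights. The mitochondrial genes, Hsp70Bb and Sr-CI passed over their lists alone whichever library was left out. EndoA was lost without Control 1, 2 or 3, Shal RNAi 1 or 3, Notch RNAi 1, 2 or 3 or Notch+Shal RNAi 1, 2 or 3 (adjusted p up to 0.144). Mctp was lost without Control 1 or 3, Shal RNAi 1, Notch RNAi 2 or Notch+Shal RNAi 2 (adjusted p up to 0.617). The gene dpr21 was lost without Control 2 or 3, Shal RNAi 1 or 3, Notch RNAi 1, 2 or 3 or Notch+Shal RNAi 1, 2 or 3 (adjusted p up to 0.162). The median log2 interaction over all genes was 0.40, and 0.01 with TMMwsp scaling.

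**Figure D3:**
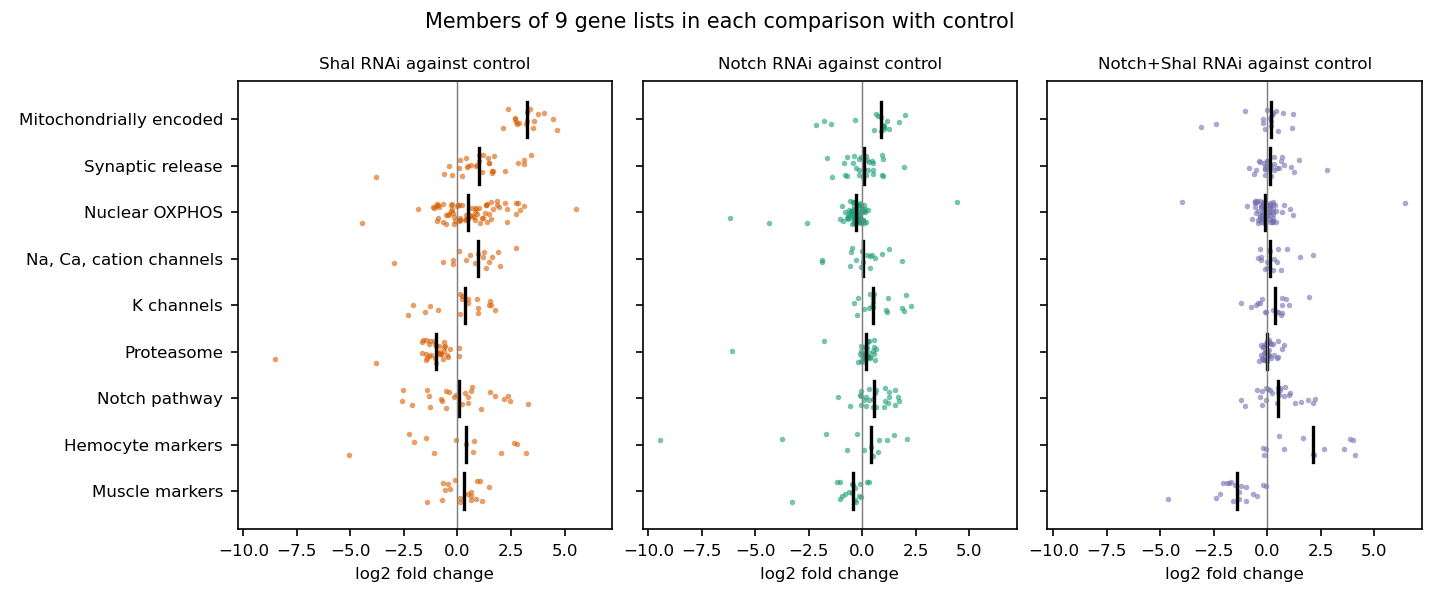
Log2 fold change (x axis) of each tested member (points) of 9 gene lists (y axis) in the 3 comparisons with control, with a black bar at each list's median. The mitochondrially encoded RNAs have medians of 3.23, 0.88 and 0.14, and muscle markers have 0.31, -0.46 and -1.44.

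Whole-transcriptome responses were also set side by side across 8908 genes, which are not independent replicates, using comparisons that share no libraries. The log2 fold changes linked to the Shal RNAi label without Notch RNAi (Shal RNAi against control) and with it (Notch+Shal RNAi against Notch RNAi) had a Pearson r of -0.0270 and a Spearman rho of -0.00945. In 100 random regroupings within each comparison r ran from -0.314 to 0.257, and 88 lay at least as far from 0. Of 43 genes at an unadjusted p under 0.05 in both, 30 moved the same way. For the Notch RNAi label without and with Shal RNAi, r was -0.0136 and rho -0.00338, r in 100 regroupings ran from -0.326 to 0.318 with 90 at least as far from 0, and 24 of 45 genes moved the same way. No gene was called in either comparison of a pair by edgeR at an adjusted p of 0.05. Neither r lay outside the range given by regrouped libraries.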

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

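The tests of low library yield, of Shal knockdown with and without Notch knockdown, of RNA from other cells, of a wrong Notch RNAi label and of Notch knockdown, the splits by unadjusted p and the fit with roX1 were chosen after the result was seen. The test of Notch knockdown replaced a planned correlation of y with N over the 7 Notch-labelled libraries, which was run and met its prediction for Notch knockdown by unadjusted p. It was then dropped because N falls into separate clusters there. In the Notch RNAi group, the only group of 4, 18 of 97 values had 1 library far from the other 3 (Dixon's test). Chance flags about 1 in 20 of normal, independent values, and these are skewed CPM of genes and lists that partly overlap, so their number is not set against chance. Of these 18, 11 lay in Notch RNAi 4. It was highest for N (294 CPM, next 23.6), w (629.8, next 7.67), numb (86.3, next 9.52), the motoneuron factor eve (273, next 27.9), the glial glutamine synthetase Gs2 (755, next 39.6), and ktub (109, next 36.1). It was also highest for Hsp27 (5092, next 1884), the glia list (923 CPM, next 133), the heat shock list (17526 CPM, next 8783) and the TMM factor (1.41), and lowest for UQCR-11 (474 CPM, next 852). Notch RNAi 1 was highest for Jhbp2 (728 CPM), CG12934 (281) and the vesicular GABA transporter VGAT (62.7), Notch RNAi 2 for mt:ATPase8 (474) and the muscle actin Act57B (485), and Notch RNAi 3 for the glial transporter Eaat1 (34.1). Notch RNAi 3 had the lowest total, 3.78 M counts against 7.53 M in the next.

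The difference linked to the Shal RNAi label was not the same with and without the Notch RNAi label by the interaction test for 13 lists at the preset correlation and for 18 genes adjusted over their lists alone, 13 of them mitochondrially encoded. No list was called with an estimated correlation (lowest adjusted p = 0.273). The list medians were -3.57 for mitochondrially encoded RNAs, -1.14 for muscle, -0.95 for pumps, -0.91 for synaptic release, -0.87 for Na, Ca and cation channels, -0.80 for potassium channels and -0.74 for receptors. They were -0.38 for oxidative phosphorylation, -0.38 for transcription factors, -0.21 for cell recognition, -0.21 for mitochondrial ribosomal proteins, 0.74 for proteasome and 2.74 for neuroblast genes. Named genes among the 18 were EndoA (-4.04), Mctp (-7.12), dpr21 (-3.75), Hsp70Bb (-3.29), mt:ATPase6 (-3.83), mt:ND1 (-4.78), mt:Cyt-b (-3.57) and Sr-CI (14.39, a fitted value and no bound), and 0 genes passed over all genes in edgeR, with 813 at an unadjusted p under 0.05, 118 by DESeq2 and 0 by limma voom.

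Mitochondrially encoded RNAs were higher in the libraries labelled Shal RNAi than in control, in 17 of 17 genes (camera adjusted p = 1.52e-21, adjusted p = 0.353 with an estimated correlation). A bias toward short or abundant transcripts as the whole cause is argued against: their median of 3.23 was at percentile 100 of 10000 nuclear lists matched on exon length and level, whose medians ran from -0.71 to 2.24 and averaged 0.54. A part from such a bias is not excluded. The matched genes were drawn separately, so the range of their medians leaves out variation that mitochondrial RNAs may share. The rise was not called in Notch+Shal RNAi (median 0.14). That cannot decide on Shal knockdown acting alike with or without Notch knockdown, as no decrease of Shal was called. Its log2 fold change was 1.72 (SE 0.83) in Shal RNAi and -0.05 (SE 0.83) in Notch+Shal RNAi. Low yield of a library may still raise the mitochondrial share: over the 10 libraries without the Shal RNAi label the share had a Spearman rho of -0.358 with genes detected (permutation p = 0.314, adjusted 0.373) and a Pearson r of -0.615 (permutation p = 0.0573), which was -0.0606 without the 2 farthest libraries. An effect of Shal RNAi without the Notch RNAi label also stays open, and the design keeps it from being told apart from yield or roX1 levels.

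N was far higher in Control 3, Notch RNAi 4 and Notch+Shal RNAi 3. A wrong Notch RNAi label is argued against, since y was at least 353 normalised CPM in the Notch-labelled libraries of these and at most 81.9 without that label. RNA from other cells may be a source: a list of 20 epithelial and septate junction genes, 18 of them tested, summed to 1587, 3412 and 2162 CPM in these 3 libraries, above every other library (562 to 1052 CPM) in 3 of 3, but in 2 of 3 by normalised CPM. A lower share of motoneuron RNA stays open too, since these libraries had the lowest VGlut, but over the 13 libraries that list had a Spearman rho of -0.269 with VGlut (permutation p = 0.373) and a Pearson r of -0.679 (permutation p = 0.0116, adjusted 0.0231), which was -0.268 without the 2 farthest. No biological explanation was tested, as the 3 libraries come from 3 groups.

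Levels of y followed the Notch RNAi label in all 13 libraries, and w was high in all Shal-labelled libraries except Notch+Shal RNAi 3 (14.5 normalised CPM) and in 1 without that label, Notch RNAi 4 (449). Larval sex as the whole cause of y is argued against: with the roX1 level as a covariate its log2 fold change in Notch RNAi was 3.89 (unadjusted p = 9.63e-05). Both genes mark transgenic chromosomes, so y and w may report the RNA interference lines themselves, which was not tested, and Notch knockdown acting on y cannot be told apart from it because N had a log2 fold change of -0.16 (SE 1.03). An exchange of Notch RNAi 4 with Notch+Shal RNAi 3 would place w. The test was to count other genes that separate the remaining libraries by the Shal RNAi label at least 4-fold. No gene other than w met that rule, so the test could not decide and the exchange stays open. Libraries were analysed as labelled, and counts without these 2 are given with the other settings.

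Other splits of the same libraries were fitted in the same way. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. Shal RNAi against control had 0 genes (highest other 1) and 1047 by unadjusted p (highest other 1012). Notch+Shal RNAi against control had 0 (highest other 0) and 382 (964), and against Shal RNAi 0 (highest other 183) and 1092 (1863). For the other 3 the real count of 0 tests nothing, as any split reaches it (highest other 8 for Notch RNAi against control, 13 for Notch+Shal RNAi against Notch RNAi and 107 for the interaction). By unadjusted p chance cannot be excluded for them. For Notch RNAi against control 24 of 35 splits reached 386 (highest other 1128), for Notch+Shal RNAi against Notch RNAi 29 of 35 reached 431 (highest other 1553), and for the interaction 34 of 100 drawn reached 813 (highest other 1643). The splits with 183 and 107 genes point to a structure of the samples other than the groups: the first sets Shal RNAi 1, Shal RNAi 3 and Notch+Shal RNAi 3 against the rest.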

How the results depend on the processing

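The fits without doubted libraries, with roX1 and with the older quasi-likelihood method were chosen after the data were seen. In simulated data with these group sizes the test recovered 18 to 36% of 16-fold changes at the dispersions of these libraries and all of them at a dispersion of 0.1. The cause of each change was not tested. EdgeR called 0 genes in all 6 comparisons, and RLE factors, the stricter filter, limma voom and the older method did too. DESeq2 called 309 for Shal RNAi, 32 for Notch RNAi and 24 for Notch+Shal RNAi against control. For Notch+Shal RNAi it called 307 against Shal RNAi and 33 against Notch RNAi, and for the interaction 118. Without a filter on low counts edgeR called 26 for Shal RNAi, 1 for Notch RNAi and 1 for Notch+Shal RNAi against control. For Notch+Shal RNAi it called 4 against Shal RNAi and 1 against Notch RNAi. TMMwsp gave 2 for Notch RNAi against control and voom with quality weights 25 for Shal RNAi against control and 1 for Notch RNAi against control. A fit of only the groups compared gave 23 for Shal RNAi against control and one without robust estimation 1 for Notch RNAi against control. With roX1 there were 4 for Shal RNAi, 2 for Notch RNAi and 1 for Notch+Shal RNAi against control, and 35 for the interaction. Without the 2 libraries whose w is out of place there were 48 for Shal RNAi against control, 1 for Notch RNAi against control, 2 for Notch+Shal RNAi against control, 25 for Notch+Shal RNAi against Shal RNAi, 1 for Notch+Shal RNAi against Notch RNAi and 14 for the interaction. Without the 3 lowest in VGlut there were 1 for Notch RNAi against control, 16 for Notch+Shal RNAi against Shal RNAi, 1 for Notch+Shal RNAi against Notch RNAi and 3 for the interaction, and without Shal RNAi 1 and 3, where the lone Shal RNAi library is assumed to vary like the other groups, there was 1 for Notch RNAi against control. Leaving out each library gave 0 to 146 for Shal RNAi against control, 0 to 2 for Notch RNAi against control, 0 to 1 for Notch+Shal RNAi against control, 0 to 26 against Shal RNAi, 0 to 2 against Notch RNAi and 0 for the interaction.

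Pairing by replicate number stays open. Of 18 same-number pairs, 5 correlated above 0.1 (-0.176 to 0.239, median 0.0721), and 45 other pairs had a median of -0.00422. Of 13 libraries, 7 correlated best with their own number. With the replicate number as a block edgeR called 1 for Notch RNAi against control, 1 for Notch+Shal RNAi against Shal RNAi and 9 for the interaction. The correlations of effects were -0.200 (Shal label) and -0.185 (Notch label), and the log2 value with the other sign was 0.12 for Shal in Notch+Shal RNAi against control.

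With an estimated correlation, and with fry, 0 lists were called in all 6 comparisons. RLE gave 5 lists for Notch+Shal RNAi against Notch RNAi, leaving out Shal RNAi 1 and 3 4 there and 8 for the interaction, and leaving out the libraries lowest in VGlut 7 for Notch RNAi against control. Leaving out each library gave 4 to 13 lists for Notch RNAi against control, 4 to 10 for Notch+Shal RNAi against control and 2 to 9 against Notch RNAi. It gave 9 to 12 for Shal RNAi against control, 9 to 13 for Notch+Shal RNAi against Shal RNAi and 9 to 15 for the interaction. The correlation of effects was -0.199 (Shal label) without the lowest in VGlut, and ran from -0.188 to 0.0391 (Shal label) and -0.178 to 0.0723 (Notch label) over left-out libraries. Of alternatives for the 58 called lists, 571 kept call and direction, 287 lost the call, 0 gained one and 6 changed direction; for the 123 gene values these were 2231, 355, 80 and 64.

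The sign changed in these cases, the cause being not tested. Log2 values with limma voom were 0.42 for Shal in Notch+Shal RNAi against control, -0.48 for N in Notch+Shal RNAi against control, -0.32 for N in Notch+Shal RNAi against Notch RNAi and 0.45 for Ser in the interaction. With sample quality weights they were -0.34 for Kr in Shal RNAi against control, and 0.12 for Kr and -1.23 for Delta in the interaction. In Notch+Shal RNAi they were 0.53 for Shal and -0.75 for N against control, and 0.0360 and -0.16 against Notch RNAi. With roX1 they were, against control, 1.18 for N in Shal RNAi and -0.52 for Shal and 2.19 for N in Notch RNAi. In the interaction they were -0.66 for N and -0.43 for Delta. Without Shal RNAi 1 and 3 they were -2.52 for moody and -2.39 for Ser in Shal RNAi against control. They were 4.65 for moody in Notch+Shal RNAi against Shal RNAi. In the interaction they were -0.39 for nerfin-1, 1.42 for Ser and 0.41 for the cell recognition list. Without the 2 libraries whose w is out of place they were 0.22 for Shal in Notch+Shal RNAi against control. For N in Notch+Shal RNAi they were -2.34 against control, -0.16 against Shal RNAi and -0.48 against Notch RNAi. In the interaction Delta had -0.11. Without the 3 lowest in VGlut they were 3.57 for Delta in Shal RNAi against control and -6.22 for Delta in the interaction. In Notch+Shal RNAi they were 0.16 for Shal and -0.75 for N against control. For N they were -0.13 there against Shal RNAi and -0.45 against Notch RNAi.

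Over left-out libraries the sign also changed, with ranges as follows. For the fat body and proteasome lists camera's direction changed and the median did not. The reverse held for the glycolysis list in Shal RNAi against control, the immune list in Notch RNAi against control, the immune list in Notch+Shal RNAi against Notch RNAi, the cell recognition list in the interaction and the mitochondrial ribosomal protein list in the interaction. Against control epsilonTry ran from -9.02 to 4.14 in Shal RNAi, -11.49 to 2.53 in Notch RNAi and -9.58 to 2.22 in Notch+Shal RNAi. moody ran from -2.45 to 11.18 in Shal RNAi against control and -9.13 to 4.57 in Notch+Shal RNAi against Shal RNAi. Delta ran from -10.26 to 3.57 in Shal RNAi against control and -3.26 to 10.52 in the interaction. Ser ran from -2.91 to 2.76 in Shal RNAi against control and -4.07 to 1.95 in the interaction. Shal ran from -0.42 to 1.12 in Notch RNAi against control, -0.70 to 0.97 in Notch+Shal RNAi against control and -0.80 to 0.13 in Notch+Shal RNAi against Notch RNAi. N ran from -1.88 to 1.38 in Notch RNAi against control and -7.35e-04 to 4.77 in the interaction. In Notch+Shal RNAi it ran from -2.34 to 2.17 against control, -0.15 to 3.87 against Shal RNAi and -2.19 to 2.58 against Notch RNAi. Against control Jon74E ran from -8.35 to 3.75 in Notch RNAi and -8.21 to 2.11 in Notch+Shal RNAi. nerfin-1 ran from -0.56 to 5.93 in the interaction. The oxidative phosphorylation list ran from -0.47 to 0.0454 in Notch RNAi against control. The glycolysis list ran from -1.48 to 0.37 in Notch+Shal RNAi against control, -0.19 to 1.02 in Notch+Shal RNAi against Notch RNAi and -0.28 to 1.66 in Shal RNAi against control. In Notch+Shal RNAi against Notch RNAi the fat body list ran from 0.39 to 1.599 and the proteasome list from -0.35 to -0.00261. The immune list ran from -0.0252 to 4.93 in Notch RNAi against control and -3.83 to 0.0970 in Notch+Shal RNAi against Notch RNAi. In the interaction the cell recognition list ran from -1.23 to 0.26 and the mitochondrial ribosomal protein list from -0.73 to 0.00704.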

Other observations

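All values in this part were picked after the data were seen, except the tests of lists. The dosage compensation RNA roX1 (FBgn0019661, chromosome X, 3857230 to 3862697), which coats the X chromosome of males, was at 1078 to 3823 CPM in Shal RNAi 2 and 3, Notch RNAi 1 and 3 and Notch+Shal RNAi 1 and 2. It was at 7.73 to 23.1 CPM in the 3 control libraries, 88.0 in Shal RNAi 1, 31.3 and 64.3 in Notch RNAi 2 and 4 and 52.5 in Notch+Shal RNAi 3. Of the larval sex list 2 genes were tested, too few for a list test. Levels of roX1 were unequal between groups, as no control library had a high level, and the sex of the larvae was not known. The comparisons with control and the interaction may carry this difference. The nucleotide sugar transporter gene senju (FBgn0031676, chromosome 2L, 5052843 to 5054575) was at most 0.407 normalised CPM in the libraries labelled Shal RNAi and at least 18.4 in the other 10, Notch+Shal RNAi included. The receptor-like gene mthl8 was at most 0.0878 normalised CPM in the 7 libraries with a Notch RNAi label and at least 8.41 in the other 6. Neither gene passed in edgeR. Levels of 1 to 4 counts in a group give no fold.

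Several lists were called in none of the 6 comparisons. They include Notch targets (lowest camera adjusted p = 0.281, median -0.73, in Notch RNAi against control) and presynaptic homeostasis genes (lowest camera adjusted p = 0.281, median 0.35, in Notch RNAi against control). The same held for interneuron markers (lowest camera adjusted p = 0.566, median -0.64, in Shal RNAi against control) and glia markers (lowest camera adjusted p = 0.0526, median 1.45, in Shal RNAi against control). It also held for the unfolded protein response (lowest camera adjusted p = 0.202, median 0.64, in Notch+Shal RNAi against Shal RNAi), RNA interference machinery (lowest camera adjusted p = 0.230, median 0.90, in Notch+Shal RNAi against Shal RNAi) and cytoplasmic ribosomal proteins (lowest camera adjusted p = 0.165, median -0.03, in Shal RNAi against control). Heat shock transcripts summed to 14161 CPM in Control 3, 17526 in Notch RNAi 4 and 15545 in Notch+Shal RNAi 2, and to at most 9029.6 elsewhere. Neuroblast and cell cycle genes summed to 2215 CPM in Notch+Shal RNAi 2 and 1778 in Notch RNAi 4, and to at most 831.6 elsewhere. Neuronal transcription factors summed to 27184 CPM in Notch RNAi 1 and at most 11691 elsewhere. Muscle markers summed to 1135, 428 and 1719 CPM in Notch+Shal RNAi 1 to 3 and 1212, 3964 and 3963 in Control 1 to 3.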
